A study of Zea mays with 4 samples.

How the data were processed

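RNA-seq was done on maize endosperm at 10 days after pollination, with 2 wild-type and 2 dek mutant libraries, A and B of each genotype. Each library was made from a pool of 8 to 10 individuals, and the repeats came from 2 segregating ears. Which pools shared an ear is not stated, so no pairing entered the model. Per the labels, total RNA was extracted with CTAB and libraries were made by standard Illumina protocols; whether poly(A) RNA was selected or strands were kept is not given in the sources used here.

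The authors deposited a table per library with a length, an estimated count and an FPKM value per gene. The expected counts are, as deposited by the authors, RSEM-style estimated counts per gene with no further normalization. The FPKM values were scaled by the authors to kilobases of effective gene length and to counted fragments, per the file headers and the values. HISAT, Bowtie2, RSEM and GATK are named by the authors without a version, order or role, and the genome build and annotation release are not given in the sources used here. Only genes with a value above 0 are listed, 34567 in any library and 26785 in all 4, and a gene missing from a table was taken as 0. Of these genes, 2988 were added by the authors to the reference gene models. Names were matched to a RefSeq table for 23676 genes, by model identifier for 17811 and by protein accession for 5865; 491 matched several RefSeq genes and 10891 matched none. Descriptions and annotation terms are those of the deposited tables.

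Counts per library ranged from 13119658 to 14776699. The gene test was edgeR 4.0.16 in R 4.3.3, a quasi-likelihood fit to the rounded estimated counts, with TMM factors of 0.895 and 0.903 for wild type A and B and 1.128 and 1.097 for dek A and B. Genes were filtered by filterByExpr, which left 24624, and a two-sided Benjamini-Hochberg adjusted p under 0.05 was the threshold. The biological coefficient of variation was 0.226. The p-values refer to variation between pools, not between individual kernels. With 2 against 2 libraries, the smallest two-sided p a permutation of labels can give is 0.333, so all p-values rest on the fitted models.

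Gene lists were fixed before the data were examined and matched by symbol or description. The endosperm lists were zeins, starch synthesis, endosperm transcription factors, and markers of the basal transfer layer, embryo-surrounding region and aleurone. The process lists were cell cycle and DNA replication, histones, cytosolic and organelle ribosomal proteins, alternative respiration, the respiratory chain, pentatricopeptide repeat proteins, splicing, endoplasmic reticulum chaperones, heat shock proteins, pathogenesis-related genes, sugar transport, fermentation, auxin, cytokinin and the proteasome. Embryo markers and photosynthesis genes stood for other tissues. After identifiers were seen and before any test, 14 genes were removed from lists because their annotation named another kind of protein. Of 24 lists, the 23 with at least 5 tested genes were tested with limma 3.58.1, by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry, with Benjamini-Hochberg adjustment over lists. Terms of 10 to 500 tested genes were tested with one-sided Fisher's exact tests in scipy 1.17.1, against tested genes with any term of the same ontology, and adjusted over terms and directions.

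Genes were named by a rule set before the data were examined. It took the 12 highest and 12 lowest fold changes past the threshold among genes with a mean of at least 10 FPKM in the higher group, libraries of each genotype on one side of the other and an informative description. It also took up to 4 members of each list past the threshold with the highest mean FPKM, or 2 members where none passed, and the genes sh2, bt2, wx1, o2, pbf1 and mn1. A few other list members were named after their values were seen, among them fl2, meg1 and genes given as the only member of a count. Where a group had no counts, a floor of 3 counts over the group was used, and with 1 to 3 counts an exact 95% Clopper-Pearson interval of the ratio.

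Alternatives were DESeq2 size factors, upper-quartile factors, total counts alone, the DESeq2 1.42.0 Wald test, limma on log2 FPKM with a pseudocount of 1 or 0.1, no low-count filter, a filter of 50 counts in 2 libraries, a replicate block by title letter or crossed, a log2 difference of at least 1, zein genes left out, and each library left out in turn. The methods were tested on simulated data of 24624 genes in which 200 were changed, 50 at each fold. The edgeR test recovered 1 of 50 genes at 1.5-fold, 7 at 2-fold, 34 at 4-fold and 46 at 8-fold. It also called 20 of 24424 unchanged genes. These false calls made up a larger share of all its calls than the adjusted p threshold sets as a target. The same held for DESeq2, with 35 false calls. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.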

Results

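RNA was sequenced from maize endosperm, the starch- and protein-storing tissue of the kernel, at 10 days after pollination. Wild-type kernels and kernels of a mutant labelled dek were compared, with 2 pooled libraries of each genotype, A and B. Each pool held 8 to 10 individuals, and the pools came from 2 segregating ears. The labels do not name the mutated gene, so its own transcript could not be used as a check of the genotype. The estimated counts summed to 14562359 and 13119658 in wild type A and B, and to 14776699 and 14703218 in dek A and B. Counts above 0 were listed for 30452 and 29569 genes in the wild-type libraries and for 31509 and 31098 genes in the mutant libraries. The 10 most abundant genes took 10.8% and 9.4% of the wild-type counts, against 6.4% and 6.8% of the mutant counts. The first principal component of log2 CPM held 71.5% of the variance and separated the genotypes. Over all genes, the libraries of a genotype correlated at r = 0.952 for wild type and 0.965 for dek, and libraries of different genotypes at 0.869 to 0.889.

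The first comparison asked which genes differed between mutant and wild-type endosperm. All 26 genes tested for zeins, the prolamin storage proteins of maize endosperm, were lower in the mutant. Of 38 starch synthesis genes tested, 21 were lower and 1 higher. Several glutathione S-transferase genes and alternative oxidase 1 were among the largest rises, while another alternative oxidase gene fell. Glutathione S-transferase 4 (GRMZM2G132093), of a family of enzymes that conjugate glutathione to reactive compounds, rose from 2.47 ± 0.01 to 325 ± 45.5 FPKM (mean ± SD, n = 2 per genotype). The delta-zein gene dzs10 (BGI_novel_G003037) fell from 10608 ± 951 to 462 ± 254 FPKM (mean ± SD, n = 2 per genotype). Of 24624 genes tested with edgeR's quasi-likelihood test, 1965 were higher and 2178 lower in dek at a Benjamini-Hochberg adjusted p under 0.05, which is 16.8% of the genes tested. Of these, 1349 higher and 1283 lower genes differed by at least 2-fold, a log2 difference of at least 1. Higher genes made up 47.4% of the calls with TMM scaling and 77.9% with scaling to total counts alone, where log2 fold changes moved up by a median of 0.307. Fold changes are given on the TMM scale, so they differ by about that shift from ratios of the FPKM values, which carry no such scaling. Calls dropped from 4143 to 746 without dek A, to 965 without dek B and to 2667 without wild type B.

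The 12 largest rises among genes with a mean of at least 10 FPKM in dek and an informative description included 4 glutathione S-transferases. GSTU6 gene GRMZM2G056388 had no counts in either wild-type library and 32.4 ± 4.28 FPKM in dek (mean ± SD, n = 2), which is at least 220-fold higher against a floor of 3 counts over the wild-type group. A second GSTU6 gene, GRMZM2G097989, rose by 4.63 ± 0.152 on the log2 scale (± SE), and glutathione S-transferase lambda2 (GRMZM2G042639) by 5.88 ± 0.501. The esterase PIR7B-like gene GRMZM2G126367 was also without wild-type counts and was at least 113-fold higher in dek by the same floor. Alternative oxidase 1 (GRMZM2G125669), a terminal oxidase that bypasses the cytochrome pathway of the mitochondrial electron transport chain, rose 206-fold from 0.13 ± 0.06 to 35.2 ± 7.16 FPKM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000416). A glyoxylate reductase (GRMZM2G159587) rose by 7.24 ± 0.403, an NF-YB-4-like transcription factor subunit (GRMZM2G152822) by 6.62 ± 0.434, a serine carboxypeptidase (GRMZM2G106165) by 4.76 ± 0.281 and a small chain of ribonucleotide reductase (GRMZM2G155546), which makes deoxyribonucleotides, by 4.54 ± 0.304. ATFP4 (GRMZM2G169726) had 1 count over the wild-type group and 306 over the mutant group, a 232-fold ratio with an exact 95% counting interval of 41.4 to 9200. The remaining gene of the 12 was a basal layer antifungal peptide gene, described with its tissue markers.

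The 12 genes with the largest falls comprised 10 alpha-zein genes and a pair of defence peptides. The antimicrobial peptide gene MBP-1 (GRMZM2G325118) had 4002 counts over the wild-type group and 1 over the mutant group, a 5270-fold ratio with an exact 95% counting interval of 946 to 208000. The subtilisin-chymotrypsin inhibitor CI-1B (GRMZM2G012806) fell from 480.4 ± 296 to 0.15 ± 0.07 FPKM, from 8948 counts to 3, a 3930-fold ratio with an interval of 1340 to 19100. Such intervals and floors cover counting error only. The 24 genes of the largest rises and falls were chosen by size from these same 4 libraries. Fits on fewer of the libraries are therefore no independent check of them. All 24 genes of the largest rises and falls passed the threshold in each of the 4 fits without 1 library. Of all 105 named genes past the threshold, 48 passed in each of those fits and 80 in each of the other scalings.

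**Figure D1:**
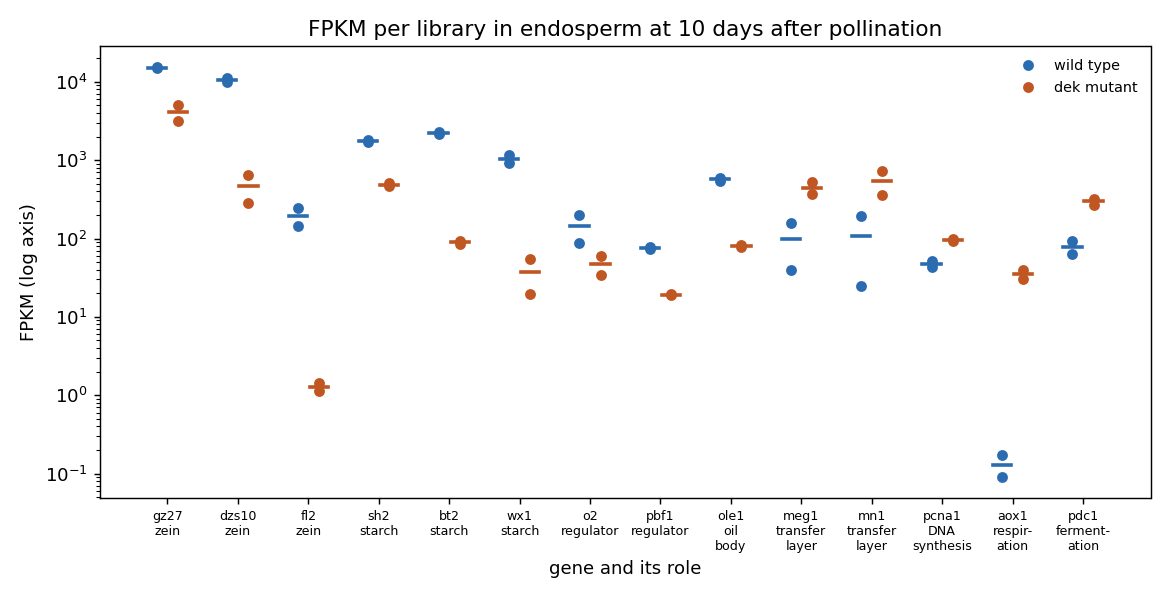
FPKM of 14 endosperm genes in each of the 4 libraries, on a log axis, with points for libraries and short lines for genotype means (n = 2). The zein and starch genes lie lower in both dek libraries, alternative oxidase 1 lies near 0.13 FPKM in wild type and 35.2 FPKM in dek, and the transfer layer genes meg1 and mn1 differ widely between the wild-type libraries.

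The fixed gene lists asked whether known endosperm programs and cellular processes moved together. Zeins fell as a whole. All 26 zein genes tested were lower in dek, with a median log2 fold change of -8.20, and all 26 were also lower when adjusted over the list alone. Their share of all counts fell from 6.10% ± 0.253 in wild type to 0.699% ± 0.240 in dek (mean ± SD, n = 2). The 27-kDa gamma-zein gene gz27 (GRMZM2G138727) fell least, from 15225 ± 459 to 4079 ± 1310.2 FPKM, or 4.71-fold. The 15-kDa zein gene zp15 (GRMZM2G086294) fell by 6.55 ± 1.16 and zp16 (GRMZM2G060429) by 5.80 ± 0.437 on the log2 scale (± SE), while the alpha-zein genes fell further. Among these, floury2 (fl2, GRMZM2G397687) fell least, by 7.54 on the log2 scale, and a 22-kDa zein gene (GRMZM2G045387) fell most, with 2372 counts over the wild-type group and 1 over the mutant group, a 3120-fold ratio with an exact 95% counting interval of 560 to 123000. Alpha-zein genes are near-identical copies among which reads can be shared, so single copies are uncertain, and the list is given as a group. The camera test with a preset correlation of 0.01 gave a Benjamini-Hochberg adjusted p of 3.21e-216 for zeins, and adjusted p = 0.108 with an estimated correlation. In each fit without 1 library, and with total-count scaling, 26 zein genes were lower.

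Starch synthesis genes were lower in part. Of 38 tested, 21 were lower and 1 higher in dek (23 and 2 adjusted over the list alone), with a median log2 fold change of -0.88. Both subunits of the endosperm ADP-glucose pyrophosphorylase, which makes the glucosyl donor for starch, were lower: shrunken2 (sh2, GRMZM2G429899) fell 4.42-fold from 1749 ± 88.9 to 488 ± 25.8 FPKM, and brittle2 (bt2, GRMZM2G068506) fell 30.3-fold from 2207 ± 102 to 89.7 ± 5.54 FPKM (mean ± SD, n = 2). The granule-bound starch synthase gene waxy1 (wx1, GRMZM2G024993) fell 34.3-fold, the sucrose synthase gene shrunken1 (sh1, GRMZM2G089713) 8.85-fold and the amyloplast ADP-glucose transporter brittle1 (bt1, GRMZM2G144081) 6.79-fold. The single higher member was a minor isoamylase 1 model (BGI_novel_G000754), with 0.93 and 0.62 FPKM in wild type and 4.23 and 5.77 in dek, named after its value was seen. Camera gave a Benjamini-Hochberg adjusted p of 1.89e-19, and adjusted p = 0.108 with an estimated correlation. Without dek A, 16 members were lower, and with total-count scaling 19 were lower and 2 higher, with a median of -0.57.

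Endosperm transcription factors that act on these genes were lower in part. Of 8 tested, 4 were lower and none higher (4 adjusted over the list alone), with a median log2 fold change of -0.52. Prolamin-box binding factor (pbf1, GRMZM2G146283), an activator of zein genes, fell 4.83-fold from 75.2 ± 3.44 to 19.2 ± 0.45 FPKM (n = 2). Opaque2 (o2, GRMZM2G015534), a bZIP activator of zeins, fell from 145 ± 81.4 to 47.4 ± 18 FPKM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0384). The NAKED ENDOSPERM genes nkd1 (GRMZM2G129261) and nkd2 (GRMZM5G884137), regulators of aleurone and starchy endosperm, fell by 1.39 ± 0.252 and 0.84 ± 0.157 on the log2 scale. Camera gave a Benjamini-Hochberg adjusted p of 0.0047 for the list, and adjusted p = 0.53 with an estimated correlation. With total-count scaling 2 members were lower and 1 higher, with a median of -0.21. Without dek A or without dek B, 1 member each passed. The nkd2 call was lost without wild type B too, and without dek B the edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) was 0.154 for o2, 0.0869 for nkd1 and 0.103 for nkd2.

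Markers of the basal transfer layer, the maternal-side cell layer that takes up nutrients, were higher in dek but varied between the wild-type pools. Of 15 tested, 3 were higher and none lower (3 adjusted over the list alone), with a median log2 fold change of 1.72. A basal layer antifungal peptide gene (GRMZM2G133382) rose from 4.74 ± 3.77 to 167 ± 45.5 FPKM (n = 2). Of 2 gene models matched to meg6, GRMZM2G094054 rose by 2.41 ± 0.582 and GRMZM2G088896 by 2.46 ± 0.576 on the log2 scale. The latter is described as a maternally expressed gene 3 precursor. The cell wall invertase gene miniature1 (mn1, GRMZM2G119689) did not pass, with 193 and 25.1 FPKM in wild type A and B and 721 and 358 in dek A and B (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.177). The list took 0.204% and 0.050% of the counts in wild type A and B, and 0.651% and 0.410% in dek A and B. Camera gave a Benjamini-Hochberg adjusted p of 1.57e-05, and adjusted p = 0.664 with an estimated correlation. The median was 3.06 with all 15 members higher without wild type A, 1.12 with 6 higher without wild type B, and 1 member, the antifungal peptide gene, passed without dek A or without dek B. The 4 embryo-surrounding region markers were too few for a list test, and none passed in edgeR or DESeq2, or at an unadjusted p under 0.05. ESR6 precursor gene GRMZM2G048353 stood at 26.4 and 6.15 FPKM in wild type and 58.6 and 48.1 in dek, and 3 of the 4 passed as higher without wild type A. Their median log2 fold change was 0.73, but -0.06 without wild type B. None of 7 aleurone markers passed in either count (median log2 fold change -0.03, limma camera Benjamini-Hochberg adjusted p = 0.971). At an unadjusted p under 0.05 the number was 2, and DESeq2 called 0. With total-count scaling 1 of the 7 was higher and none lower, with a median of 0.28. Pale aleurone color 1 (GRMZM2G058432) had 107 ± 5.14 FPKM in wild type and 136 ± 16.4 in dek, and sal1 (GRMZM2G117935) 66.6 ± 7.6 and 67.3 ± 0.03 (n = 2).

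**Figure D2:**
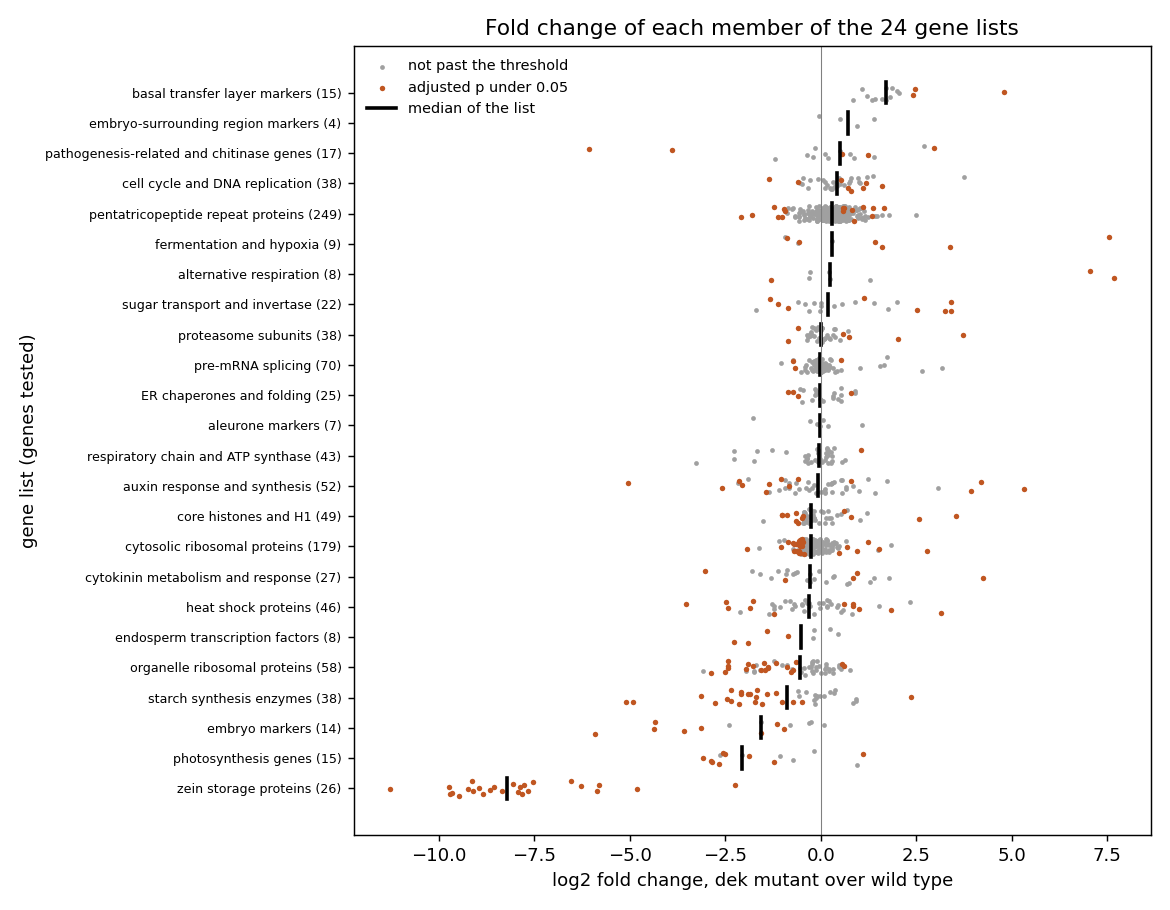
Log2 fold change, dek over wild type, of each tested member of the 24 gene lists, with members past an adjusted p of 0.05 in orange and the list median as a black bar. All 26 zeins lie below -2.23, and the transfer layer list has the highest median at 1.72.

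Respiration genes outside the standard electron transport chain included some of the largest rises. Of 8 genes of alternative respiration, 2 were higher and 1 lower (2 and 1 adjusted over the list alone). Besides alternative oxidase 1, a gene (GRMZM2G090487) matched to the list as an external NAD(P)H dehydrogenase had 0.03 FPKM in both wild-type libraries and 8.1 and 3.16 in dek, with 2 and 386 counts, a 147-fold ratio with an exact 95% counting interval of 40.3 to 1210. A second alternative oxidase gene (GRMZM2G102349) fell 2.44-fold from 16.5 ± 2.25 to 8.66 ± 0.71 FPKM (n = 2), a call lost without dek A or dek B. The list had a median log2 fold change of 0.24 and a mean of 1.83, with a camera Benjamini-Hochberg adjusted p of 0.0217, and adjusted p = 0.442 with an estimated correlation. The list call was lost without wild type B (camera Benjamini-Hochberg adjusted p = 0.0526), and the median was -0.13 without dek B. Of 43 genes of the respiratory chain and ATP synthase, 1 was higher and none lower (1 and none adjusted over the list alone): a ubiquinol-cytochrome c reductase subunit (GRMZM2G171476) rose 2.09-fold, with an edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.0739 without dek B. That list's median was -0.04 (camera Benjamini-Hochberg adjusted p = 0.811), or 0.27 with total-count scaling, where 7 members were higher and none lower, and 6 members were lower without wild type A.

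Genes of fermentation and low oxygen moved both ways. Of 9 tested, 4 were higher and 2 lower (4 and 3 adjusted over the list alone), with a median log2 fold change of 0.29 and a camera Benjamini-Hochberg adjusted p of 0.0513. Pyruvate decarboxylase genes pdc1 (AC197705.4_FG001) and pdc3 (GRMZM2G087186) rose from 78.4 ± 22 to 297 ± 35.7 FPKM and from 78 ± 3.03 to 258 ± 58.7 FPKM, while pdc2 (GRMZM2G038821) fell from 57.5 ± 3.71 to 38.7 ± 2.96 FPKM (mean ± SD, n = 2). The glyceraldehyde-3-phosphate dehydrogenase gene gpc3 (GRMZM2G071630) fell by 0.58 ± 0.141 on the log2 scale, a call that was lost with total-count scaling and without any 1 library. The pdc1 call was lost without dek B and the pdc2 call without dek A or dek B. The list passed camera with total-count scaling (limma, Benjamini-Hochberg adjusted p = 0.0475) and with zein genes left out (0.0485). With an estimated correlation, where no list passed in these settings, limma camera adjusted p (Benjamini-Hochberg) was 0.631 and 0.671. Without 1 library the list's median ranged from 0.14 without wild type B to 0.44 without wild type A. Sugar transport and invertase genes had 5 higher and 3 lower of 22 (7 and 4 adjusted over the list alone; median 0.18; camera Benjamini-Hochberg adjusted p = 0.291). The sucrose transporter gene sut1 (GRMZM2G034302) rose by 1.12 ± 0.275 and a hexose transporter gene (GRMZM2G153704) fell by 1.13 ± 0.191 on the log2 scale. Both calls were lost without dek A or dek B, and that of sut1 also without wild type B. With total-count scaling 8 members were higher and 2 lower, with a median of 0.49.

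Cell cycle and DNA replication genes shifted upward by a small amount. Of 38 tested, 6 were higher and 2 lower (9 and 4 adjusted over the list alone), with a median log2 fold change of 0.41. The replication clamp gene pcna1 (GRMZM2G030523) rose 1.64-fold from 47.2 ± 5.42 to 95.9 ± 2.88 FPKM, and the catalytic subunit of DNA polymerase delta (GRMZM2G115245) 1.45-fold from 15.4 ± 1.37 to 27.4 ± 1.98 FPKM (n = 2), while the retinoblastoma-related gene rbr3 (GRMZM2G033828) fell by 0.60 ± 0.135 on the log2 scale. Camera gave a Benjamini-Hochberg adjusted p of 0.0203, and adjusted p = 0.442 with an estimated correlation. With total-count scaling 17 members were higher and none lower, and no member passed without dek A, while 1 was higher without dek B, and 1 was higher and 1 lower without wild type B. The polymerase call was lost without any 1 library, and those of pcna1 and rbr3 without any but wild type A. Core histone and H1 genes had 4 higher and 8 lower of 49 (6 and 16 adjusted over the list alone; median -0.24; camera Benjamini-Hochberg adjusted p = 0.291), and with total-count scaling 11 were higher and 2 lower. Histone H4 gene GRMZM2G332838 fell 1.83-fold and H3 gene GRMZM2G051879 1.55-fold. Both belong to families of near-identical copies, and the H3 call was lost without any 1 library and the H4 call without any but wild type A.

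Ribosomal protein genes were slightly lower on the TMM scale. Of 179 cytosolic ribosomal protein genes, 6 were higher and 22 lower (5 and 19 adjusted over the list alone), with a median log2 fold change of -0.25 that became 0.05 with total-count scaling, where 22 were higher and 4 lower. Camera gave a Benjamini-Hochberg adjusted p of 0.00954 for the list, adjusted p = 0.675 with an estimated correlation, and adjusted p = 0.091 without dek A. Examples were 60S protein L28-1-like (GRMZM2G394827), which fell by 0.64 ± 0.122, and 40S protein S3a (GRMZM2G013457), which fell by 0.69 ± 0.137; both calls were lost without any 1 library other than dek B. Organelle ribosomal protein genes had 18 lower and 2 higher of 58 (21 and 2 adjusted over the list alone; median -0.53; camera Benjamini-Hochberg adjusted p = 0.000328, and adjusted p = 0.62 with an estimated correlation). The 50S protein L9 gene GRMZM2G096962 fell 2.58-fold from 31.6 ± 2.93 to 15.1 ± 1.04 FPKM (n = 2), while 50S protein L33 gene GRMZM2G176133 rose 1.52-fold, a call held only without wild type B among the fits without 1 library. With total-count scaling 11 were lower and 4 higher, with a median of -0.22, and the 44 nuclear-encoded members had a median of -0.23 on the TMM scale. Members lower numbered 2 without dek A, 3 without dek B and 5 without wild type B. Pentatricopeptide repeat genes, whose proteins process organelle RNA, had 9 higher and 7 lower of 249 (4 and 4 adjusted over the list alone; median 0.29; camera Benjamini-Hochberg adjusted p = 0.0491, and adjusted p = 0.461 with an estimated correlation). That call was lost without any 1 of the 4 libraries and with total-count scaling, where 43 members were higher and 4 lower. GRMZM2G396752 of this list rose by 0.60 ± 0.134, and GRMZM2G017145 fell by 1.23 ± 0.16 on the log2 scale, the first call being lost without any 1 library and the second without dek A or dek B.

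Heat shock genes moved both ways. Of 46 tested, 6 were higher and 6 lower (8 and 11 adjusted over the list alone; median -0.30; camera Benjamini-Hochberg adjusted p = 0.333). The 17.8-kDa class II small heat shock gene GRMZM2G034157 fell from 852 ± 385 to 193 ± 141 FPKM and a stromal heat shock gene (GRMZM2G001500) from 262 ± 21.2 to 89.2 ± 4.12, whereas HSP81-1-like gene GRMZM2G112165, of the HSP90 family, rose 1.99-fold from 221 ± 23.8 to 544 ± 20.7 FPKM (n = 2). The list's median was -0.475 without wild type A and 0.08 without wild type B. With total-count scaling it was 0.01, with 9 higher and 5 lower. The small heat shock gene's call was lost without wild type B or dek A. Chaperones of the endoplasmic reticulum had 1 higher and 3 lower of 25 (1 and 3 adjusted over the list alone; median -0.02; camera Benjamini-Hochberg adjusted p = 0.952), among them a protein disulfide isomerase (GRMZM2G091481), which fell 1.82-fold, and calreticulin 2 (crt2, GRMZM2G358059), which rose 1.72-fold; the first call was lost without wild type A or dek B, and the second without wild type A, dek A or dek B. That list's mean log2 fold change was 0.05, opposite in sign to its median, and 2 members were higher and none lower with total-count scaling. Pathogenesis-related and chitinase genes had 3 higher and 2 lower of 17 (4 and 2 adjusted over the list alone). Their median was 0.50 and their mean 0.04 (camera Benjamini-Hochberg adjusted p = 0.811). Without 1 library the median ranged from 0.03 without dek A to 0.47 without dek B. Pathogenesis-related protein 2 (prp2, GRMZM2G102356) fell 15-fold from 82.5 ± 2.61 to 6.82 ± 3.68 FPKM, and endochitinase PR4 (GRMZM2G129189) rose 7.87-fold from 1.1 ± 0.08 to 10.7 ± 0.47 FPKM (n = 2).

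Hormone lists did not shift as a whole. Auxin genes had 4 higher and 9 lower of 52 (5 and 11 adjusted over the list alone). Their median was -0.06 (camera Benjamini-Hochberg adjusted p = 0.446). Without 1 library it ranged from -0.32 without wild type B to -0.01 without wild type A. The tryptophan aminotransferase-related gene tar3 (GRMZM2G141810) fell 6.04-fold from 285 ± 27.2 to 58 ± 22.6 FPKM and auxin response factor 15-like (GRMZM2G030710) 2.54-fold (n = 2), the second call being lost without dek A. Cytokinin genes had 3 higher and 2 lower of 27 (3 and 3 adjusted over the list alone; median -0.27; camera Benjamini-Hochberg adjusted p = 0.811), with cytokinin-O-glucosyltransferase 3 (GRMZM5G854655) 8.11-fold lower. Proteasome subunits had 4 higher and 2 lower of 38 (4 and 2 adjusted over the list alone; median 0.02; camera Benjamini-Hochberg adjusted p = 0.717), and an alpha subunit gene (GRMZM2G005080) rose 1.67-fold, a call lost without dek A or dek B. Splicing genes had 1 higher and 2 lower of 70 (none adjusted over the list alone; median -0.02; camera Benjamini-Hochberg adjusted p = 0.971), with small nuclear ribonucleoprotein G (GRMZM2G083642) 1.6-fold lower, a call lost without any 1 library. The splicing list's mean was 0.11, opposite in sign to its median. With total-count scaling the medians of the auxin, cytokinin and splicing lists became 0.25, 0.04 and 0.29, with 8 auxin genes higher and 6 lower, 3 cytokinin genes higher and 1 lower, and 5 splicing genes higher and none lower. Proteasome subunits then had 10 higher and 1 lower.

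Markers of other tissues asked whether embryo or green maternal tissue differed between the pools. Embryo markers were lower in dek. Of 14 tested, 8 were lower and none higher (9 lower adjusted over the list alone), with a median log2 fold change of -1.56, and the list took 0.202% ± 0.029 of the counts in wild type and 0.074% ± 0.003 in dek (mean ± SD, n = 2). The oil-body protein gene ole1 (GRMZM2G337229) fell 8.78-fold from 572 ± 33.8 to 80.3 ± 3.35 FPKM, and globulin 3 (glb3, GRMZM2G410134) 2.94-fold from 833 ± 177 to 349 ± 49 FPKM; oleosins and globulins are also made in aleurone. The embryo regulator lec1 had 2.88 and 0 FPKM in wild type and 1.01 and 1.07 in dek and did not pass (GRMZM2G011789, chosen after its value was seen). Camera gave a Benjamini-Hochberg adjusted p of 1.69e-12, and adjusted p = 0.123 with an estimated correlation; without dek B, 5 of the 18 members then tested were lower. Photosynthesis genes were lower as well, with 8 lower and 1 higher of 15 (11 and 2 adjusted over the list alone; median -2.06; camera Benjamini-Hochberg adjusted p = 0.000719, and adjusted p = 0.442 with an estimated correlation). The most abundant member, pyruvate orthophosphate dikinase ppdk1 (GRMZM2G306345), is also an endosperm enzyme and fell 2.35-fold from 1399 ± 154 to 712 ± 136 FPKM. The photosystem members stood at low levels, such as the photosystem II 47-kDa protein gene GRMZM2G427444 with 3.77 and 17.1 FPKM in wild type and 2.75 and 2.61 in dek, a call lost without dek A or dek B. By their descriptions, 5 of the 15 were transcripts of the plastid genome, of which 3 were lower, with a median of -2.64, and the other 10 had 5 lower and a median of -1.15. The higher member (GRMZM2G005433) is described as a pentatricopeptide repeat protein. Without dek A or without dek B, 1 photosynthesis gene each was lower and none higher.

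Annotation terms gave the same comparison without chosen lists, over all gene ontology and KEGG orthology terms in the deposited tables. Of 1509 terms tested in each direction, 26 were over-represented among higher genes and 29 among lower genes (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). Among lower genes, plastid stroma led, with 115 of 430 genes against 46.7 expected by chance (Fisher's exact test, Benjamini-Hochberg adjusted p = 1.73e-17), followed by plastid envelope, with 92 of 374 against 40.6. Higher genes numbered 25 in plastid stroma and 28 in plastid envelope. Starch metabolic process had 17 of 34 lower genes against 3.7 expected, fatty acid metabolic process 23 of 81 against 8.8, and protease subunits of the ATP-dependent Clp protease 8 of 17 against 1.5. Endopeptidase inhibitors had 10 of 25 lower against 2.6 expected. The best expressed of these inhibitors, a trypsin/factor XIIA inhibitor (GRMZM2G304548), stood at 2759 and 3104 FPKM in wild type and 719 and 1255 in dek.

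Among higher genes, the glutathione S-transferase orthology group led, with 17 of 41 genes against 3.4 expected by chance (Fisher's exact test, Benjamini-Hochberg adjusted p = 5.25e-06). IMP biosynthesis, the pathway of purine synthesis, had 8 of 10 genes higher against 0.9 expected (Fisher's exact test, Benjamini-Hochberg adjusted p = 4.4e-05), and its best expressed member, a phosphoribosylformylglycinamidine cyclo-ligase (GRMZM2G160925), stood at 45.3 and 46.2 FPKM in wild type and 91.1 and 94.7 in dek. The microtubule cytoskeleton had 29 of 131 genes higher against 10.7 expected, and 7 lower. Its best expressed member was the alpha-tubulin gene GRMZM2G152466, at 725 and 723 FPKM in wild type and 1507 and 1662 in dek. Tubulin beta genes had 8 of 20 higher and none lower, and tricarboxylic acid metabolism 7 of 11 higher and 1 lower. Cell wall genes went both ways, with 35 of 207 higher against 17 expected by chance, and 30 lower. These examples were taken as the members past the threshold with the highest mean FPKM, a rule set after the values were seen. When the terms were tested with genes past an adjusted p of 0.01, 5 terms among higher and 14 among lower genes passed. In all, 13 terms passed at both thresholds. Fisher's exact test takes genes as independent of each other, so its p-values do not measure spread between pools. Terms were not tested under other scalings or without 1 library.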

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

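All alternatives below were set before the data were examined. No gene past the threshold was called in the opposite direction in any of them. With DESeq2 size factors, upper-quartile factors, DESeq2, no or a stricter low-count filter, a crossed replicate block or zeins left out, gene counts stayed within 1.5 times the reported 1965 higher and 2178 lower. Total counts alone gave 4502 higher and 1279 lower, and limma on log2 FPKM gave 4462 and 1315 with a pseudocount of 1 and 4071 and 1228 with 0.1. These 3 settings carry no TMM factor and shift log2 fold changes up by 0.281 to 0.307; the limma settings also change the values, the test and the filter, and what part each plays was not tested. A log2 difference of at least 1 kept 2632 genes, 1283 of them lower, and 67 named genes. The title letter as a block gave 1891 genes, 811 higher and 1080 lower, and 67 named genes. The A minus B differences of both genotypes correlated across genes at -0.022, which gives no sign of pairing by letter. Leaving out 1 library gave 746 to 3697 genes, 281 to 1731 higher, 465 to 1966 lower, and 51 to 78 of the 105 named genes. These fits have fewer samples, and the lone library is assumed to vary like the other genotype. Without a dek library the spread comes from the wild-type pair, the more variable 1 of the 2 pairs. The A minus B differences had an SD of 0.75 in wild type and 0.6 in dek. Whether this alone is why leaving out a dek library costs more calls was not tested. Of the lists, 9 fixed and 2 other-tissue lists passed camera with a preset correlation, and 0 and 0 with camera with estimated correlation. With fry, which does not compare a list with other genes, 5 and 1 passed. The estimated correlation was 0.956 for the transfer layer list. It was 0.003 for starch synthesis and -0.024 for the cell cycle and embryo lists, below the preset 0.01. A higher correlation is therefore not what cost these 3 lists their calls. Even the zein list, with all 26 members lower, did not pass with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p = 0.108). A call lost in that test therefore does not tell lists apart. Terms fell from 55 to 19 with genes at adjusted p under 0.01, where fewer genes enter. Over all alternatives, 1341 of 1635 values of named genes kept their direction and side of the threshold, 286 lost the call, 3 gained it and 5 without a call moved. Of 183 list results by camera with the preset correlation, 155 kept camera's direction and side of the threshold. Another 14 without a call changed direction, 9 lost and 5 gained a call. The median itself could change sign where camera's direction did not, as for histones, from -0.24 to 0.06 with total-count scaling. On simulated data with this depth and spread, in which 200 of 24624 genes were changed, 14% of 2-fold changes were recovered. In the data 4143 genes passed, and the adjusted p is less strict where more genes change. The recovery in these data was therefore not measured, and small changes can still be missed. False calls made up a larger share of the simulated calls than the threshold sets as a target. Their share in these data was not measured either.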

Other observations

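The gene families and all 6 tests of explanations below were chosen after the results were seen. The 18 families were picked by description and tested in both directions, 36 tests in all. As in the term tests, Fisher's exact test took genes as independent of each other. WRKY and NAC were the transcription factor families over-represented among higher genes, and MYB among lower genes. WRKY transcription factors, a family known from defence and senescence, had 12 of 50 genes higher in dek against 4.0 expected by chance, and none lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00397). WRKY gene GRMZM2G148561 rose from 2.28 and 2.14 FPKM in wild type to 28.7 and 16.2 in dek. NAC transcription factors had 15 of 56 higher and 3 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.000399 for higher), and NAC gene GRMZM2G104078 rose by 2.50 ± 0.264 on the log2 scale (± SE). Cytochrome P450 genes had 17 of 92 higher and 7 lower (adjusted p = 0.00631 by the same Fisher's exact test), among them a P450 72A13-like gene (GRMZM2G014395) at 13.5 and 18.5 FPKM in wild type and 129 and 96.1 in dek.

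Kinesins, motor proteins that move along microtubules, had 13 of 48 genes higher and 2 lower, or 24 higher and 1 lower with total-count scaling. Expansins, which loosen cell walls, had 6 of 18 higher and 4 lower, with beta-expansin 7 (GRMZM2G342246) rising by 3.50 ± 0.529 on the log2 scale. Aminotransferases, enzymes of amino acid metabolism, had 12 of 27 lower and none higher, or 10 lower and 4 higher with total-count scaling. These 3 families share genes with annotation terms that had already passed, so only their counts are given. Alanine aminotransferase gene GRMZM2G088064 fell from 1047 and 963 FPKM in wild type to 368 and 420.4 in dek. MYB genes had 16 of 86 lower and 6 higher (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.017), but 12 lower and 13 higher with total-count scaling.

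Basal transfer layer markers stood higher in the dek pools. The change in the mean zein share raises the log2 share of other genes by 0.081, far below the lowest list median of 1.12 in the fits without 1 library, which argues against it. The 2 wild-type libraries differed from each other over the list by a median log2 ratio of 1.94, A over B, more than the median of 1.72 between genotypes. Pools that hold different amounts of basal kernel tissue may therefore account for a difference of this size. A change in the transfer layer of the mutant itself stays open and was not tested.

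Transcripts of the plastid genome stood lower in dek, with a median log2 fold change of -2.13 over 31 tested and 17 past the threshold. Without wild type B the median was -1.43, and without wild type A -2.52, which argues against wild type B alone setting the difference. Less RNA without poly(A) tails carried into the mutant libraries could lower mitochondrial genome transcripts too, and these had a median of -1.03, with 53 of 53 below 0 but 2 past the threshold. That median lies between the bounds set for and against this explanation, and without 1 library it ranged from -1.60 without wild type A to -0.49 without wild type B, with -1.52 without dek A, so such a loss and a change in plastids themselves cannot be told apart. Nuclear-encoded organelle ribosomal protein genes had a median of -0.23, or 0.08 with total-count scaling.

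All 26 zein genes and 21 of 38 starch synthesis genes were lower in dek, and 1 starch synthesis gene was higher. Both list calls were lost with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p = 0.108 for each). With fry, which does not compare a list with other genes, both lists passed as lower (limma fry, Benjamini-Hochberg adjusted p = 0.00827 for each). A joint fall of both lists was not tested. The zein list's share of all counts, which moving reads between copies does not change, fell from 6.10% in wild type to 0.699% in dek. The 6 zeins outside the alpha family all fell as well, with a median log2 fold change of -5.83. Both values argue against reads shared among alpha-zein copies as the cause of the zein fall. Mutant endosperm at an earlier stage of development might show higher cell cycle and histone genes. The cell cycle list passed camera as higher (limma camera, Benjamini-Hochberg adjusted p = 0.0203, and adjusted p = 0.442 with an estimated correlation), but the histone median was -0.24 and did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.291), so a delay cannot be told apart from a direct loss of storage gene expression. A later time point was not analysed here.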
